A study of Homo sapiens with 2 samples.

How the data were processed

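Gene expression was measured on 2 Affymetrix arrays hybridised with biotin-labelled cRNA, 1 from MKN28 cells labelled as overexpressing Sox2 and 1 from MKN28 cells labelled as control. The array is the human expression array with 54675 probe sets, each a group of short probes that reads 1 stretch of a transcript. Per the labels' protocols, cells were infected with a lentivirus carrying Sox2 and selected with puromycin, and total RNA was extracted with Trizol. The labels do not say what, if anything, the control cells received.

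The deposited values are probe set intensities on a linear scale, with 1 value per probe set and array. RMA is the only tool that the submitters' processing notes name, and its version and settings are not given in the sources used here. The deposited intensities ranged from 1 to 19811 in the array labelled Sox2 and from 1 to 19501 in the array labelled control, with medians of 34.25 and 34.26. RMA usually ends in log2 values with 1 distribution for all arrays. The deposited columns were linear and, once sorted, differed by up to 1585, so the last step that made them is not known here. Scanner images and probe-level intensities were not used here, so no detection call per probe set could be made.

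Values were taken to log2 as they stood, with a lowest intensity of 1 (16 values in the array labelled Sox2 and 13 in the other). No further scaling was applied in the main analysis, since the median log2 difference over all probe sets was -0.0027. Probe sets were named through the platform annotation, which is some years old, with symbols updated through Entrez identifiers to the RefSeq gene table of assembly GRCh38.p14. Of 19777 identifiers, 19735 matched that table. Leaving aside the 62 Affymetrix control probe sets, which entered no gene value, exactly 1 gene was listed for 41091 probe sets, several for 1801 and none for 11721. Some genes of the fixed lists have no named probe set here and were not analysed.

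Each gene was represented by its probe set with the highest mean log2 value. A gene entered when the higher of its 2 values reached the median of all probe set values (an intensity of 34.25), which left 14253 of 19775 genes. With 1 array per group no test between the conditions is possible, so genes were counted by a fixed size, a difference of at least 2-fold, and no p-value is given. The 23 gene lists, the size rule and the alternatives were fixed before the data were examined. For each list the median log2 difference was placed among 10000 random lists of the same size matched on mean level in 20 bins. This percentile describes these 2 arrays and is no test of the conditions. The genes named are SOX2, the 12 with the largest difference in each direction among genes whose other probe sets past the filter, if any, differed in the same direction, and of each list up to 4 members with differences of at least 2-fold, or the 1 with the largest difference where none reached it. Genes named only to describe levels, such as keratins, were chosen after their values were seen. So were AXIN2 among the Wnt targets, SOX7 in the SOX family and FOS, FOSB, JUNB and JUND among the immediate early genes.

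The only spread these data give is technical. From 3471 genes with 2 probe sets past the filter, the robust SD of the log2 difference of 1 probe set was 0.27. It leaves out variation between cultures and between arrays. Across genes, the robust SD of the differences was 0.28 for all genes past the filter. It was larger at both ends of the level range, 0.49 in the dimmest bin and 0.69 in the brightest. A 2-fold difference of a bright gene therefore stands out less than 0.27 would imply. These values across genes include any real difference between the arrays. The counting and list procedures were tested on simulated data built from the 14253 genes, with the observed spread at each level and 200 changed genes. A true change of 1.5-fold was counted for 3% of changed genes, of 2-fold for 47.5%, of 3-fold for 96.5% and of 4-fold for 100%. Between 144 and 163 unchanged genes were counted in each simulation. The simulated spread came from the observed differences between the 2 arrays, which hold any real difference between them. The simulation therefore cannot say how many of the genes counted in the data are noise. The number of arrays limits the precision of all values.

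Alternatives covered the choice of probe set, probe sets that may cross-hybridise, the filter on dim genes, median and lowess centring (span 0.3), quantile normalization and the fold threshold. Removal of a trend with genomic length and a filter at the 90th percentile were added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6. Plots used matplotlib 3.10.9.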

Results

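The study compared MKN28, an established human gastric adenocarcinoma cell line, with and without overexpression of SOX2, a transcription factor of stem cells and of the foregut and stomach epithelium. MKN28 is listed as a misidentified derivative of another gastric line, MKN74. RNA from 1 sample labelled Sox2 and 1 labelled control was read on 1 array each. There were no replicates, so every difference below is between 2 arrays and has no replicate error. The intensities of the 2 arrays correlated across probe sets, which are not independent replicates, with a Pearson r of 0.964 on the log2 scale. Signal was low: the 95th percentile of the intensities was 162 in the array labelled Sox2 and 156 in the array labelled control, against medians of 34.25 and 34.26.

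EPCAM was read at a low level in both arrays. The brightest probe sets of the epithelial keratins KRT8, KRT18 and KRT19 lay between the median and the 95th percentile of all probe sets. Genes common to most cells were read at very different levels by different probe sets. EPCAM, an epithelial surface protein, had intensities of 4.96 in the array labelled Sox2 and 6.32 in the other. KRT8 had 50.25 and 44.64, and KRT18 had 70.12 and 88.53. KRT19 had 40.57 and 37.71 by its brighter probe set and 20.64 and 16.12, below the median, by another. CDH1, the epithelial cadherin, reached 78.58 and 91.27. VIM, the intermediate filament protein of mesenchymal cells, had 5833 and 4288 by 1 probe set and 10.73 and 9.45 by another. Of the 27 epithelial adhesion genes with a probe set, only TJP1 had a brightest probe set above the 95th percentile of all probe sets, at 1919 and 1187, against 8 of 28 mesenchymal and fibroblast genes. The typical level did not separate these lists: the median percentile of the brightest probe set was 77.7 for the epithelial adhesion genes and 75.2 for the mesenchymal and fibroblast genes. This measure ranks the brightest probe set of each gene among all probe sets, which favours high percentiles. It gave 66.6 for the leukocyte and endothelial genes, so it does not show that the genes of a list are expressed.

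EEF1A1, a translation elongation factor, read 10957 and 10700 and TUBA1B, an alpha tubulin, 10516 and 9990 by their brightest probe sets, while the brightest probe sets of 14 tubulin genes had medians of 137 and 151. The control probe sets of ACTB, the cytoplasmic actin, read 4935 and 3582 near its 5′ end but 103 and 91.1 near its 3′ end. Those of GAPDH, a glycolytic enzyme, read 1202 and 1451 near the 5′ end and 184 and 195 near the 3′ end. The 10 probe sets of mitochondrially encoded mRNAs, which are abundant in human cells, lay between 3.46 and 33.7, all below the median of all probe sets. Probe sets differ in how strongly they bind, so these levels do not rank transcripts by abundance. All 24 probe sets of the poly-A spike-ins, bacterial transcripts added to the RNA before labelling, were lower in the array labelled Sox2, with a median log2 difference of -0.75.

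**Figure D1:**
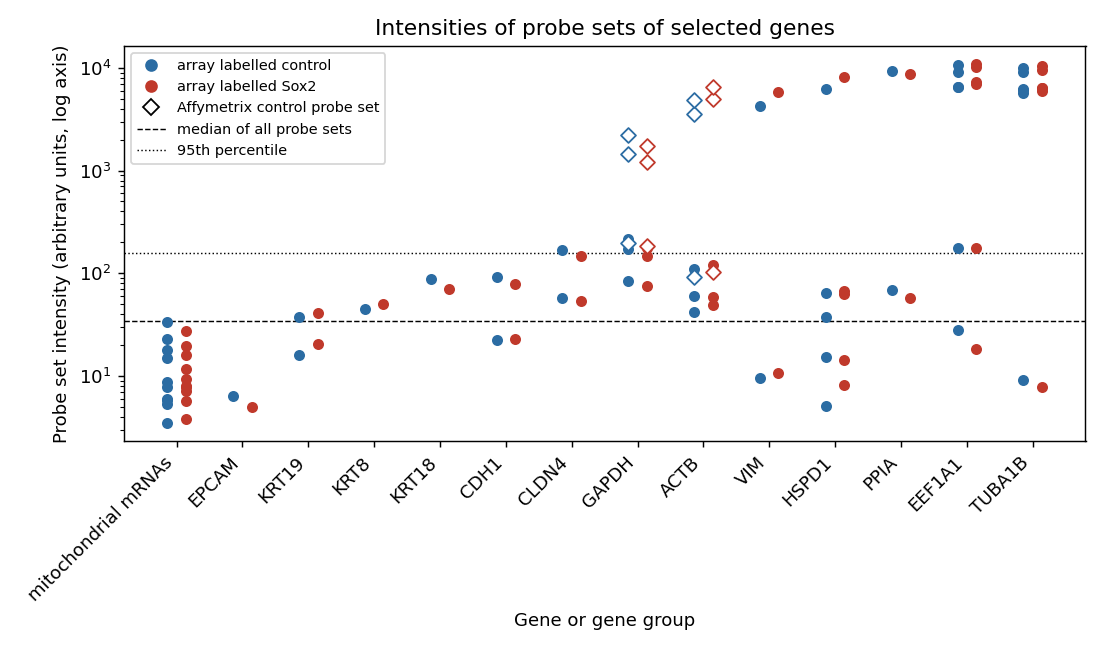
Probe set intensity in arbitrary units on a log axis for the 10 probe sets of mitochondrial mRNAs and for selected genes, with 1 point per probe set in the array labelled control (blue) and in the array labelled Sox2 (red), and open diamonds for Affymetrix control probe sets. EPCAM, at 4.96 and 6.32, and the mitochondrial mRNAs lie below the dashed line, the median of all probe sets, while VIM, EEF1A1 and TUBA1B each have probe sets far above it and others below.

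SOX2 itself was not read at a clearly higher level in the array labelled Sox2. Its brightest probe set read 172 there and 123 in the control, a log2 difference of 0.49 or 1.40-fold, against a technical SD of 0.27. A second read 27.4 and 22.2 (0.31), another 38.4 and 39.1 (-0.023), and the last 11.4 and 15.7 (-0.46). Of these, the ones with differences of 0.49 and -0.023 passed the filter on dim probe sets. Where the 4 probe sets lie relative to the transferred sequence is not known here, and the label of the array could not be checked by its target gene. The arrays are therefore named by their labels throughout, and every direction below rests on those labels.

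Between the arrays, 292 of 14253 genes were at least 2-fold higher in the array labelled Sox2 and 92 were at least 2-fold lower, which is 76.0% higher among those counted. The other 13869 genes, 97.3%, differed by less than 2-fold. The genes counted as higher were long, with a median genomic length of 67061 bases, and those counted as lower short, with 11707, against 24437 for all genes past the filter. The largest differences were taken among genes whose other probe sets past the filter, if any, differed in the same direction. That those probe sets lie on 1 side therefore follows from the rule. MCM4 (4.19-fold) and EGR1 (3.88-fold) were higher by more but were left out by it. Among the 12 largest differences upward so taken were USP38, a deubiquitinase, at 408 against 117 (3.49-fold), and CDK8, a kinase of the Mediator complex, at 256 against 81.6 (3.14-fold). Another was HES1, a Notch target and transcriptional repressor, at 434 against 145 (2.99-fold). HSPA5, the main chaperone of the endoplasmic reticulum, read 1769 against 593 (2.98-fold), ERRFI1, a feedback inhibitor of the EGF receptor, 554 against 186 (2.98-fold), and MECOM, a zinc finger transcription factor, 386 against 131 (2.96-fold). Also among them were NUP155 (3.06-fold), PLAA (3.02-fold), NCBP1 (2.92-fold) and 3 genes near the filter. The last were CCNE2 (35.7 against 10.1), NSMCE3 (68.6 against 20.8) and BAG4 (54.7 against 17.4). On the log2 scale, other probe sets past the filter differed by 1.77 for CDK8 and 0.78 for PLAA. For HES1 the difference was 0.41, for HSPA5 0.18 and for MECOM 0.93 and 0.058.

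The 12 largest differences downward were taken by the same rule. Among them, HINT2, a mitochondrial hydrolase, read 146 in the array labelled Sox2 against 521 in the control, 3.56-fold lower. MVB12A, of the endosomal sorting machinery, read 105 against 366 (3.48-fold lower), and FABP5, a fatty acid binding protein, 120 against 387 (3.21-fold lower). H2AC8, a replication-dependent histone, read 118 against 357 (3.03-fold lower), MRPL54, a mitochondrial ribosomal protein, 57.9 against 163 (2.81-fold lower), and PSMB3, a proteasome subunit, 110 against 289 (2.63-fold lower). The others were HELQ (2.81-fold lower), GALK1 (2.67-fold), FOSL2 (2.64-fold), CENPT (2.63-fold) and 2 genes near the filter, AFAP1 at 12.3 against 45.4 and LINC00943 at 16.8 against 44.7. Second probe sets past the filter differed much less, by -0.19 for GALK1, -0.092 for FOSL2 and -0.17 for CENPT on the log2 scale.

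Counts of this kind depend on the rule. Averaging all probe sets of a gene left 63 genes higher and 43 lower, and quantile normalization gave 213 and 117, which is 64.5% higher among those counted. Between 144 and 163 genes were counted among simulated unchanged genes. Their simulated spread was taken from these same differences, so that number does not say how many counted genes are noise. Of 232 counted genes with several probe sets past the filter, 129 had all of them on 1 side. The share among genes not counted was not taken, so this number does not show that counted genes agree better than others.

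Among the lists fixed beforehand, immediate early genes held the most members with a 2-fold difference. Of 22 members past the filter, 4 were higher, none lower and 18 under 2-fold. EGR1, a growth factor-induced zinc finger protein, read 254 against 65.6 (3.88-fold), KLF6 442 against 153 (2.89-fold), FOSL1 104 against 39.2 (2.65-fold) and JUN 606 against 240 (2.53-fold), the last 2 subunits of AP-1. Other AP-1 subunits were mixed. JUND was lower by less than 2-fold, at 2126 against 3728, and JUNB read 50.4 against 53.6. FOSB read 48.7 against 43.6 and FOS, under the filter, 16.8 against 11.5. FOSL2, outside this list, was among the largest differences downward, but its other probe set past the filter differed by only -0.092 on the log2 scale. The list's median log2 difference of 0.13 lay at percentile 95.7 of random lists. A second EGR1 probe set went the other way, at 79.1 against 140, while for KLF6 the 4 probe sets past the filter all lay above 0. The other JUN probe sets past the filter differed by 0.92 and 0.0073.

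Stress genes were mixed. In the heat shock list, HSP90AA1, the inducible cytosolic chaperone, read 1450 against 605 (2.40-fold, with 0.66 on the log2 scale by its other probe set past the filter), and 9 of 10 members were under 2-fold. That list's median of 0.37 lay at percentile 95.9. In the unfolded protein and amino acid stress list, HSPA5 and PDIA4, a disulfide isomerase at 558 against 269 (2.08-fold), were higher and 19 of 21 members were under 2-fold, with a median of -0.077 at percentile 16.4. A second PDIA4 probe set read 48.5 against 54.2, and a second HSPA5 probe set 59.6 against 52.8.

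In the proliferation list, 2 of 24 members were at least 2-fold higher and none lower, with a median of 0.11 at percentile 95.5. The median was -0.0059 (percentile 54.35) when probe sets were averaged and -0.034 (percentile 37.3) without probe sets ending in _x_at or _s_at. The 2 genes were CCNE2, a cyclin of S phase entry, near the filter, and MCM4, a subunit of the replicative helicase, at 343 against 81.9 (4.19-fold). The 3 other MCM4 probe sets past the filter differed by -0.31, 0.15 and 0.035. Of 20 apoptosis regulators, BCL2L1, which blocks apoptosis, was higher at 117 against 45.2 (2.59-fold), with the median of 0.086 at percentile 90.04. The other BCL2L1 probe sets past the filter differed by 1.32 and 0.12. None of 20 CDK inhibitors and p53 targets reached 2-fold, with the largest difference for PHLDA3 at 126 against 72.6 and a median of -0.059 at percentile 24.9.

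Lists that stand for cell identities held few differences, but most of their genes were read at low levels. The brightest probe set lay above the 95th percentile of all probe sets for 0 of 19 SOX family and 4 of 21 pluripotency genes. The same held for 1 of 26 gastric, 1 of 27 intestinal and 1 of 19 squamous and basal genes. A missing 2-fold difference therefore does not show that such genes were unchanged. Of 14 SOX family genes and 17 pluripotency genes, none reached 2-fold, and their medians of -0.076 and 0.017 lay at the 21.6th and 60.7th percentiles. The largest difference in the SOX family was that of SOX17, at 31.2 against 46.9. SOX7, at 39.7 against 27.5, also differed more than SOX2. Among the pluripotency genes the largest was that of KLF4, a reprogramming factor, at 333 against 234. None of 20 gastric epithelial genes reached 2-fold, with GKN1 at 34.9 against 24.7 as the largest (median 0.014, percentile 61.1). Nor did any of 21 intestinal genes, with MUC2 at 37.6 against 57.2 as the largest (median -0.054, percentile 28.3), or any of 14 squamous and basal genes, with SPRR1A at 55.9 against 90.7 (median -0.15, percentile 4.24).

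Of 17 neural progenitor genes, HES1 alone reached 2-fold (median -0.084, percentile 17.0), and its other probe set past the filter differed by 0.41. Of 22 mesenchymal and fibroblast genes, ZEB2, a repressor of epithelial genes, was higher at 299 against 137 (2.18-fold), with a median of 0.0043 at percentile 43.9. The other ZEB2 probe sets past the filter differed by 0.96, 0.65 and -0.056. None of 22 epithelial adhesion genes reached 2-fold, with RAB25 at 45.1 against 77.1 as the largest (median -0.036, percentile 33.4). None of 17 leukocyte and endothelial genes did, with KDR at 36.45 against 49.99 (median 0.071, percentile 81.5).

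Of the 23 lists, 2 had medians below the 2.5th percentile of random lists and none lay equally far in the other tail, though some did under alternatives. Immediate early genes reached percentile 99.95 with no filter, heat shock genes 99.8 with averaged probe sets, and apoptosis regulators 99 with the filter on the mean. In the lower tail, squamous and basal genes reached percentile 1.45 with the filter at the 75th percentile. Wnt targets had a median of -0.18 at percentile 1.09: 13 of 17 members lay below 0, but none differed by 2-fold. ASCL2, an intestinal stem cell factor, read 60.9 against 94.3, and AXIN2, a feedback inhibitor of the pathway, 77.0 against 99.7. Histones had a median of -0.37 at percentile 0.16, with H2AC8 at least 2-fold lower, H2BC5 at least 2-fold higher by 1 probe set (155 against 73.4, 2.11-fold) but lower by another (25.02 against 36.24), and 7 of 9 members under 2-fold. Taking each gene's probe set with the largest difference moved the Wnt list to percentile 11.25 and the histones to percentile 7.65. Histone genes are near-identical copies, so single members are uncertain. Beside proliferation, the medians of the apoptosis, unfolded protein, NF-kB, interferon, pluripotency, gastric, neural, mesenchymal, epithelial adhesion and reference lists changed sign under at least 1 alternative.

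In the remaining lists differences were small or single. LATS2, a Hippo pathway kinase, was the 1 of 14 YAP targets at 2-fold, at 1255 against 518 (2.42-fold, list median 0.056, percentile 73.4), and its 2 other probe sets past the filter differed by 0.13 and -0.22. LIF, a cytokine, was the 1 of 19 NF-kB and inflammatory genes, at 144 against 62.1 (2.31-fold, list median -0.0084, percentile 52.3). None reached 2-fold among 24 interferon response genes (OAS2 58.9 against 92.4, median 0.0092, percentile 61.3), 23 hypoxia and glycolysis genes (KDM3A 138 against 77.3, median 0.096, percentile 89.0) or 16 cholesterol synthesis genes (FDPS 62.2 against 90.8, median 0.035, percentile 68.7). Nor did any of 16 reference genes, where YWHAZ differed most at 4666 against 2699 (median 0.025, percentile 44.9).

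**Figure D2:**
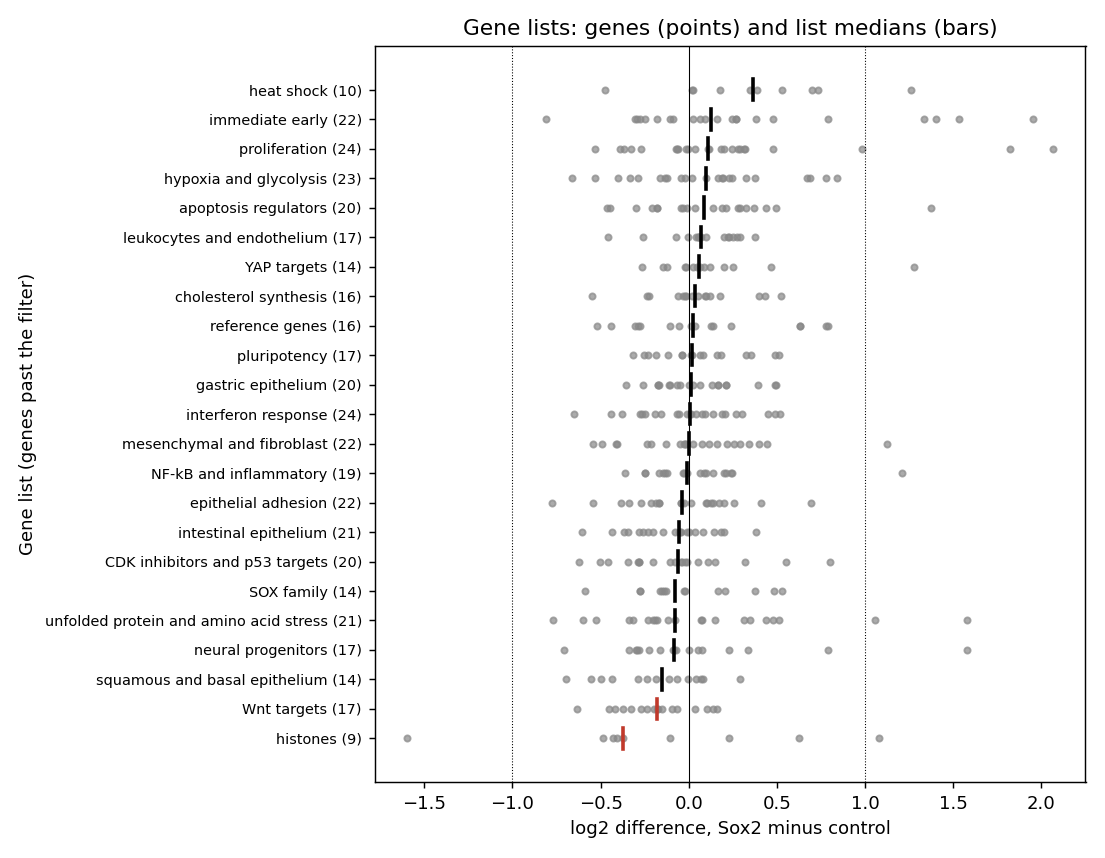
log2 difference, Sox2 minus control, of the genes of the 23 lists (grey points, number of genes past the filter in brackets) with the list medians as bars, in red where the median lay below the 2.5th percentile of random lists of matched level, and dotted lines at a 2-fold difference. Only the histones, at -0.37, and the Wnt targets, at -0.18, have red bars.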

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

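In this part the tests of 3′ end loss, of swapped labels and of the place of the SOX2 probe sets, and the use of the mitochondrial mRNAs against a human source, were chosen after the result was seen; the other tests were set before. Some signals lay outside the probe sets compared: 41 of 5245 probe sets with no gene listed and 17 of 1076 that name several genes were at least 2-fold higher in the array labelled Sox2 than in the control, against 19 and 13 lower. Among the Affymetrix control probe sets the highest log2 difference was 0.95, for the 3′ end of the small-subunit ribosomal RNA. All 24 poly-A spike-in probe sets were lower in the array labelled Sox2, with a median log2 difference of -0.75, while the hybridisation controls differed by a median of 0.15. Scaling the arrays on the spike-ins would thus shift all genes upward by 0.75.

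The first pattern is that in both arrays actin and GAPDH probe sets were far dimmer at the 3′ than at the 5′ end. In both, EPCAM was dim while single probe sets of VIM and some tubulins were very bright. The epithelial adhesion list as a whole, at a median percentile of 77.7, was no dimmer than the mesenchymal list at 75.2. That measure does not show that either list is expressed. Loss of 3′ ends in labelling would lower the 3′ over 5′ ratio of the poly-A spike-ins too. Their median ratio was at least 2.24 in each array, with a range from 1.38 to 5.26 between spike-ins. In the arrays labelled Sox2 and control the ratio was 0.021 and 0.025 for actin and 0.15 and 0.13 for GAPDH. The undisturbed spike-in ratio is not known here, but its 3.82-fold range is smaller than these gaps. The values argue against loss in labelling as the source of the actin and GAPDH ratios. Loss before the spike-ins were added was not tested. RNA of another species, read only where its sequence matches the human probes, is a candidate explanation that predicted dim mitochondrial mRNAs, and their median lay at the 9.34th percentile of all probe sets with the brightest at the 44.5th. Levels of different probe sets do not compare directly, however, and abundant genes whose sequence differs between mammals had their median at the 86.9th percentile with a 95% bootstrap interval of 74.5 to 97.6, S100A6 at 2871 and 3603 but LGALS1 at 24.0 and 28.5. Another species predicted a mitochondrial median below the 95th percentile, which was met. Human cells of another type predicted a median of those abundant genes at or above the 95th, against below the 90th otherwise. The value of 86.9 lay below the 90th. Its interval spans both bounds, but it describes only the spread between the 27 chosen genes and not the uncertainty about the source of the RNA. The brightest mitochondrial probe set also lay below the 90th, a bound chosen after the result was seen. Because levels of different probe sets do not compare directly, another species, human cells of another type and a mixture stay open. The Alu control probe set, a primate repeat, read 2534 and 1832.

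The second pattern is the SOX2 reading itself. The differences of its probe sets past the filter, 0.49 and -0.023, were under 2-fold in either direction. They decide neither whether the labels were swapped nor whether the probe sets lie outside the transferred sequence, because their places in the gene are not known here. A wrong label on a single array, and a low level of SOX2 in the infected cells, stay open as well.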

How the results depend on the processing

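No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Of the 292 genes higher and 92 lower, averaging all probe sets of a gene gave 63 and 43 (58 and 42 of them shared), leaving out probe sets ending in _x_at or _s_at 172 and 61, a 1.5-fold threshold 921 and 537, and a 3-fold threshold 14 and 5. Without the filter 177 genes were lower, and a threshold of 3 robust SDs at each level gave 267 and 146, of which only 147 and 55 were shared. The filter at the 90th percentile and the removal of a trend with genomic length were chosen after seeing the data. They and the other settings gave counts within 1.5 times of the first. The SOX2 difference of 0.49 became 0.077 as a mean of its probe sets, and -0.023 and -0.46 by 2 single probe sets. PDIA4 turned to -0.16 without probe sets ending in _x_at or _s_at, and no other named gene at 2-fold changed sign. List medians moved by over 1 SD of random lists in 36 of 242 cases; the cause was not tested. With the probe set of largest difference they became -0.22 (SOX family), -0.078 (pluripotency), -0.27 (squamous), -0.17 (intestinal), -0.022 (apoptosis), -0.22 (adhesion), -0.13 (mesenchymal), 0.19 (leukocytes), -0.20 (neural), 0.082 (interferon), 0.16 (YAP) and -0.24 (histones). With the filter at the 75th percentile they became -0.24 (squamous), 0.015 (proliferation), 0.19 (apoptosis), 0.055 (neural), 0.12 (NF-kB), 0.27 (immediate early) and 0.19 (hypoxia). At the 90th they became -0.11 (gastric), -0.28 (CDK inhibitors), 0.29 (apoptosis), 0.076 (neural), 1.34 (immediate early), 0.24 (hypoxia) and 0.14 (cholesterol). Averaging probe sets gave -0.0059 (proliferation) and -0.028 (apoptosis), no filter 0.016 (proliferation), 0.069 (unfolded protein) and 0.20 (immediate early), and the filter on the mean 0.16 (apoptosis). Leaving out _x_at and _s_at gave -0.034 (proliferation), -0.17 (unfolded protein) and 0.20 (hypoxia), and quantile normalization 0.011 (hypoxia). The histone and Wnt medians lay below 0 in all settings that gave a value. Lists with fewer than 5 members past the filter gave none: the histones at both stricter filters and without _x_at and _s_at, and at the 90th percentile also the SOX family, squamous, intestinal, Wnt, leukocyte, interferon, NF-kB and YAP lists. Signal limits the rest: 68.5% of genes past the filter had intensities under 100 in both arrays.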

Other observations

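The families of genes and the test of removing a trend with length in this part were chosen after the values were seen, while the test on bright genes was set before. Of 11 families looked at, splicing factors of the SRSF and HNRNP kind and nuclear transport receptors had the highest percentiles in the array labelled Sox2, with most members under 2-fold. Of 28 splicing factors of the SRSF and HNRNP families, 25 lay above 0 and 3 were at least 2-fold higher, with a median log2 difference of 0.57 (percentile 100 among random lists of matched level). HNRNPC, which binds nascent transcripts, read 561 against 257, and HNRNPA2B1 read 7321 against 3854. Of 21 nuclear transport receptors, 17 lay above 0 and 6 were at least 2-fold higher, with a median of 0.52 (percentile 100). TNPO3, which imports splicing factors, read 617 against 193, and KPNA1, an importin alpha, 345 against 126. Of 16 nucleoporins 13 lay above 0 (median 0.27, percentile 99.8), with NUP153 at 746 against 309. Of 7 translation initiation factors of the eIF4 group 4 lay above 0 and 3 below (median 0.57, percentile 98.0), with only EIF4G1, at 1108 against 404, reaching 2-fold. Proteasome subunits (median -0.031, percentile 14.9), USP deubiquitinases (0.066, percentile 88.9), ZNF genes (0.014, percentile 85.5) and TMEM genes (-0.050, percentile 5.62) had smaller medians, but with the filter at the 90th percentile the USP median was 0.57 and the proteasome median 0.17. Of 30 proteasome subunits, PSMD1 (802 against 303) and PSMD2 (1912 against 721) were at least 2-fold higher and only PSMB3 was at least 2-fold lower.

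Most genes of ribosomes and respiration lay below 0 on the deposited scale, by less than 2-fold, though a shift of all genes by the 0.75 of the spike-ins would put their medians above 0. Of 50 cytosolic ribosomal protein genes 47 lay below 0, with a median of -0.32 (percentile 0), and only RPL27, at 1711 against 3626, reached 2-fold. Of 57 respiratory chain genes 45 lay below 0 and 3 were at least 2-fold lower (median -0.23, percentile 0). These were NDUFB2 at 171 against 423, UQCR11 at 144 against 314 and ATP5MC2 at 622 against 1253. Of 65 mitochondrial ribosomal protein genes 46 lay below 0 (median -0.089, percentile 2.11). The signs of the medians of the splicing, transport, nucleoporin, ribosomal and respiratory groups were kept under median centring, lowess centring and quantile normalization, where the ribosomal protein median ranged from -0.44 to -0.32 and that of the splicing factors from 0.38 to 0.58. With the filter at the 90th percentile the nucleoporin median was 0.59, the respiratory median -0.43 and the mitochondrial ribosomal median -0.23. The eIF4 median fell to 0.34 under quantile normalization. Ribosomal proteins have many processed copies in the genome, so single members are uncertain.

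A further pattern was that longer genes tended to be higher in the array labelled Sox2, with 128 genes at least 2-fold higher and 11 lower among the longest, the top of 5 equal groups, and 13 and 35 among the shortest. Across genes, which are not independent replicates, the rank correlation of the difference with genomic length was 0.15, and the 0.28 among genes at or above the 90th percentile of level argues against a few dim probe sets as its source. Removing the fitted trend left 91.9% of the counted genes in place, but that trend spanned only 0.12 on the log2 scale, too little to undo a 2-fold difference, so this decides nothing about length as a cause. A bias with length, the length of the mature transcripts (not used here), RNA handling and an effect of SOX2 itself stay open. Since each group is 1 array, handling and group cannot be told apart.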
